A study of Folsomia candida with 12 samples.

How the data were processed

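Springtails of the species Folsomia candida were exposed to soil in separate glass jars, and the total RNA of whole animals from each jar was labelled with Cy3 and hybridised to 1 array of a custom Agilent design. The 12 arrays formed 4 groups of 3, named per the labels LUFA, TCA, HMF and FDCA. FDCA is 2,5-furandicarboxylic acid according to the series title, HMF was read as 5-hydroxymethylfurfural from that context, and TCA was left as an abbreviation because the labels do not expand it. LUFA was taken as the control because its label names a soil and no compound, although the labels call the soil of all 4 groups spiked. Doses were not given in the sources used here. Replicate numbers follow the order of deposition only and pair nothing between groups.

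Per the file headers, the array files hold spot signals as intensity on the linear scale, made with Agilent Feature Extraction 10.7.3.1 with spatial detrending on and local background correction off. The processed signal of each spot was the starting value. The authors also deposited a table of log2 values and named limma without a version. That table correlated with quantile-normalised log2 median spot signals at r of at least 0.998 on each array, across probes, which are not independent replicates. The largest difference between both sets of values was 2.23, and 11.8% of the values lay within 0.01 of each other, so the exact steps of the authors remained unknown. The median of the authors' log2 values was 6.600, 6.605 and 6.604 for the LUFA arrays, 6.604, 6.600 and 6.601 for TCA, 6.604, 6.601 and 6.601 for HMF, and 6.601, 6.604 and 6.596 for FDCA. These near-equal medians go with a common scaling of the arrays, and whether a centring step was also applied stayed unknown.

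The design held 35302 probes besides 1417 control spots, which were left out together with spots marked as outliers by the scanner software. Signals were put on the log2 scale, and the 75th percentile of each array was subtracted. A probe was kept when it was well above background, by the mark of the scanner software, on at least 3 of the 12 arrays. This kept 27795 probes and left out 7507. Of the kept probes, 864 lacked a value on at least 1 array because of an outlier spot, and 26931 were complete. Gene names are the best-hit descriptions that the array files pair with the probes, with the probe identifiers of the files. Among all probes 13942 had a description and 21360 were given as unknown. None of the 12496 accessions of the best hits was found in the reference table of proteins (0 matches), and no genome was used here, so no coordinates are given.

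Each of the 6 comparisons between groups was a contrast of 1 linear model over all 12 arrays, fitted per probe with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Error ranges of differences are 95% confidence intervals of that model. Where all 3 arrays of a group were not above background, the fold is given as a lower bound, with that group set on each array to the lowest signal marked well above background, and no fold is given where this held for both groups or where the bound was not above 1. The number of arrays limits the precision. On simulated data made from 27713 probes, 50 probes were changed at each size. The HMF against LUFA fit recovered 4% of the probes changed by 1 log2 unit, 66% at 2, 90% at 3 and 98% at 4. The same shares were 6%, 68%, 90% and 94% for TCA against LUFA and 6%, 62%, 90% and 94% for FDCA against LUFA. With so few changed probes, the adjusted threshold is stricter than in a comparison that calls many. These shares therefore do not give the recovery in the real comparison of HMF with LUFA.

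A total of 22 gene lists were written as search patterns on the descriptions before the data were examined, and so were the tests, the rule for named genes and all alternatives not stated to be later. The lists were cytochrome P450s, aldehyde and alcohol metabolism, phase II conjugation, carboxylesterases and epoxide hydrolases, drug and organic solute transporters, heat shock proteins and chaperones, antioxidant and metal-binding proteins, cuticle and moulting, vitellogenesis and oogenesis, digestive proteases and glycosidases, and immune recognition and effectors. The others were beta-lactam biosynthesis, fatty acid and lipid metabolism, the mitochondrial respiratory chain, cytosolic ribosomal proteins, the proteasome, DNA replication and cell cycle, DNA repair, muscle, nervous system and neurotransmission, haemolymph and storage proteins, and genes with a best hit in Wolbachia. Lists were tested with limma's camera on the complete probes with a preset correlation of 0.01 between genes, which asks whether a list moved relative to all other probes. Adjustment was over 22 lists and 6 comparisons. Camera was repeated with the correlation estimated from the data, and limma's fry, which asks whether a list moved on balance in 1 direction, was run beside it. Per-array list values are the median deviation of a list's probes from their mean over all arrays, and their differences between groups carry 95% intervals from a spread pooled over the 4 groups. A further 5 lists were added after the data had been seen.

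Named genes followed a fixed rule. In each comparison with LUFA, the rule took the 10 largest rises and the 10 largest falls among called and described probes whose 3 treated values all lay on 1 side of all 3 LUFA values, with at most 3 of the same description. Between compounds it took 5 in each direction, and where no probe was called it took the 5 smallest p in each direction, stated not to pass. It also took the 4 members with the smallest adjusted p in each list, and the text names only some of these. Calls of some members not named below ended under several alternatives, such as FCTS_17553 and FCTS_26629 for HMF against LUFA. The rule was read strictly, so a probe that lacked 1 of the 6 values was not eligible, which left synaptotagmin 1 out of the comparison of HMF with LUFA.

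The alternatives were quantile normalisation, scaling by the array median, normexp background correction with an offset of 50 followed by 75th percentile or quantile scaling, no filter, a filter for signal on all 12 arrays, slide as a fixed or random block, a fit of only the 2 groups compared, the authors' values, a trended and robust prior, the mean over probes with the same best hit, and leaving out each array in turn. Leaving out probes that hold adapter sequence, widening 2 list patterns and leaving out single arrays for the added lists were added after the data had been seen. Adapter sequence was taken as a match to the first 7 bases of a sequencing adapter. The 12 arrays lay on 3 slides of 4. Slide 1 held 1 array of each group, slide 2 held LUFA 2, TCA 2, FDCA 2 and FDCA 3, and slide 3 held LUFA 3, TCA 3, HMF 2 and HMF 3. HMF and FDCA therefore shared slide 1 alone, and differences within each shared slide are given beside the results.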

Results

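Gene expression was measured in whole springtails, small soil-dwelling arthropods, after 2 days in soil. The 12 arrays fell into 4 groups of 3, with about 30 animals of 23 days of age from 1 jar behind each array. The 75th percentile of the spot signals was 390, 370 and 313 in LUFA, 356, 303 and 310 in TCA, 419, 479 and 327 in HMF, and 258, 235 and 311 in FDCA, in units of intensity. Between 68.9% and 77.3% of the probes were well above background on each array, and 0 probes were saturated. Across probes, which are not independent replicates, replicate arrays correlated at r between 0.909 and 0.9746, and arrays of different groups at r between 0.846 and 0.974. The first principal component held 33.8% of the variance and the second 16.1%. On the first component the HMF arrays lay between 82.0 and 134, and the 9 other arrays lay between -111 and 22.3.

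**Figure D1:**
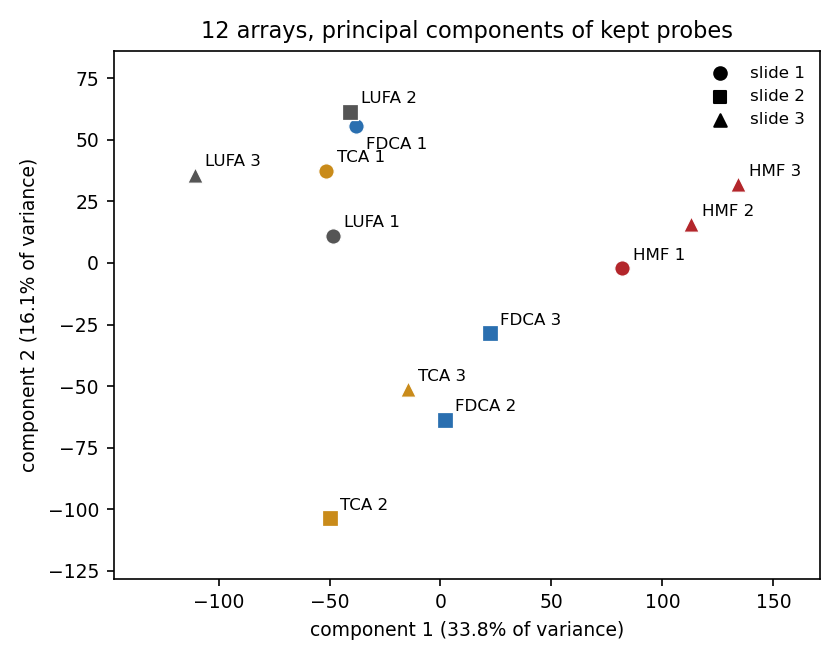
Each dot is 1 array, placed by its first (33.8% of the variance) and second (16.1%) principal component, with colour for the group and a label for the replicate. The 3 HMF arrays sit at 82.0, 113 and 134 on the first axis, and no other array lies above 22.3.

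The comparison of HMF with LUFA asks which genes respond to 5-hydroxymethylfurfural, a furan that carries an aldehyde and a hydroxymethyl group. Probes for histones H4 and H1 rose in the animals kept with HMF, and endo-beta-glucanase probes fell. As groups, camera called genes for DNA copying higher and genes for muscle proteins and cytochrome P450 enzymes lower, each with adjusted p = 0.507 with an estimated correlation. In these lists 38 of 68, 42 of 94 and 32 of 121 probes passed in that direction. Of all 12347 described probes 2848 passed higher and 1562 lower. In limma's test 9496 of 27727 probes passed, 5109 higher and 4387 lower, and 7840 of them differed at least 2-fold. A block for slide gave 10201 probes, 5356 higher and 4845 lower. The arrays of both groups did not overlap for 49.8% of the probes, against 10% by chance. The count was 6201 without HMF 2 and 5450 without HMF 3. The median over all probes was -0.11 on the log2 scale, the reference for the list medians of this comparison.

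Among called and described probes whose HMF and LUFA values did not overlap, histone H4 gave the largest rise with HMF. This core protein of the nucleosome (FCTS_1568) averaged 3.88 ± 0.92 (SD, n = 3) in HMF and -1.03 ± 1.47 (SD, n = 3) in LUFA on the log2 scale relative to the 75th percentile. This difference of 4.91 (95% interval 2.96 to 6.85) was a 30-fold rise with an adjusted p of 0.00396. Histone H1, which binds the DNA between nucleosomes (FCTS_3358), rose 18.4-fold, by 4.20 (2.74 to 5.66, adjusted p = 0.00366). Within slides the rise of histone H4 was 3.81 on slide 1 and 6.92 on slide 3, and that of histone H1 was 3.38 and 5.00. Probes described as acyl carrier protein, which holds growing fatty acid chains, rose by 4.00 (FCTS_15335) and 3.78 (FCTS_12720). Transcription factor IIIA, needed for the genes of 5S ribosomal RNA (FCTS_23358), rose by 3.66, and a homolog of the cell polarity scaffold PATJ (FCTS_15572) rose by 3.76. A zinc finger protein with a C3HC4 domain (FCTS_6729) rose by 3.85. A probe described as an omega subunit of RNA polymerase (FCTS_3116) rose 21.2-fold and one described as star protein (FCTS_16797) 14.9-fold, but both calls ended when probes of the same best hit were averaged, with 0.70 (adjusted p = 0.297) and 0.22 (adjusted p = 0.62). Another zinc finger protein (FCTS_10859) rose by 3.65 (adjusted p = 0.0246). Its call ended without HMF 1, HMF 2 or HMF 3 (adjusted p of 0.0528, 0.0561 and 0.0724) and with only both groups in the fit (adjusted p = 0.0698). On LUFA arrays 6 of these 10 probes were above background on only 2 of 3 arrays. Leaving out LUFA 3 moved 9 of these 10 folds by over 1.5 times, to 17.9 for histone H4, 8.90 and 8.76 for FCTS_15335 and FCTS_12720, 8.32 for FCTS_6729, 6.35 for FCTS_23358, 6.04 for FCTS_15572, 10.2 for FCTS_3116, 5.23 for FCTS_16797 and 3.91 for FCTS_10859. Without LUFA 2 the same 9 folds lay between 21.6 and 49.5, and without LUFA 1 that of FCTS_10859 was 19.8. All 10 passed with slide as a block, with adjusted p between 0.00833 and 0.0228.

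Among the probes chosen in the same way, an endo-beta-glucanase gave the largest fall with HMF. This enzyme, which cleaves glucan chains of plant and fungal walls (FCTS_13518), averaged -3.12 ± 1.16 (SD, n = 3) in HMF and 1.46 ± 0.40 (SD, n = 3) in LUFA. This difference of -4.57 (95% interval -6.59 to -2.55) was a 23.8-fold fall with an adjusted p of 0.00515. It was -3.80 on slide 1 and -5.24 on slide 3. Falls were also found for a further endo-beta-glucanase (FCTS_26349, -3.92), a family 30 glycosyl hydrolase (FCTS_14398, -3.86), a family 71 glycosyl hydrolase (FCTS_5338, 13.4-fold) and a chitin-binding protein (FCTS_12845, 12.8-fold). An esterase lipase (FCTS_13487) fell by 3.83 with an interval of -5.04 to -2.63. A probe described as bacterial leucyl aminopeptidase, an enzyme that removes residues from protein ends (FCTS_13515, -3.85), fell as well. So did tyramine oxidase, which oxidises amines (FCTS_7428, -3.65), a serine protease (FCTS_9141, -3.51) and a probe described as dbh-like 1 (FCTS_6641, -3.89). With the mean over probes of the same best hit, 4 of these 10 calls ended, at -0.41 for leucyl aminopeptidase (adjusted p = 0.447), -0.91 for tyramine oxidase (adjusted p = 0.13), -2.68 for the serine protease (adjusted p = 0.278) and -0.90 for dbh-like 1 (adjusted p = 0.104). The call of dbh-like 1 also ended without LUFA 3 (adjusted p = 0.061) or HMF 3 (adjusted p = 0.0824), and that of the serine protease without HMF 3 (adjusted p = 0.0504). Without HMF 3 the folds were 15.7 for FCTS_13518, 9.64 for dbh-like 1, 7.88 for tyramine oxidase and 6.67 for the serine protease. All 10 passed with slide as a block, with adjusted p between 0.00833 and 0.00853. On TCA 2, an array without HMF, some of these probes were also near their HMF values. FCTS_13518 was at -1.82, FCTS_26349 at -2.34 and leucyl aminopeptidase at -1.48. There dbh-like 1 was at 3.99 and the family 30 glycosyl hydrolase at 4.57. On TCA 1 and TCA 3 FCTS_13518 was at 1.62 and 1.66, and dbh-like 1 at 9.00 and 7.82. Low values of these probes were thus not confined to HMF arrays, and the cause was not tested.

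**Figure D2:**
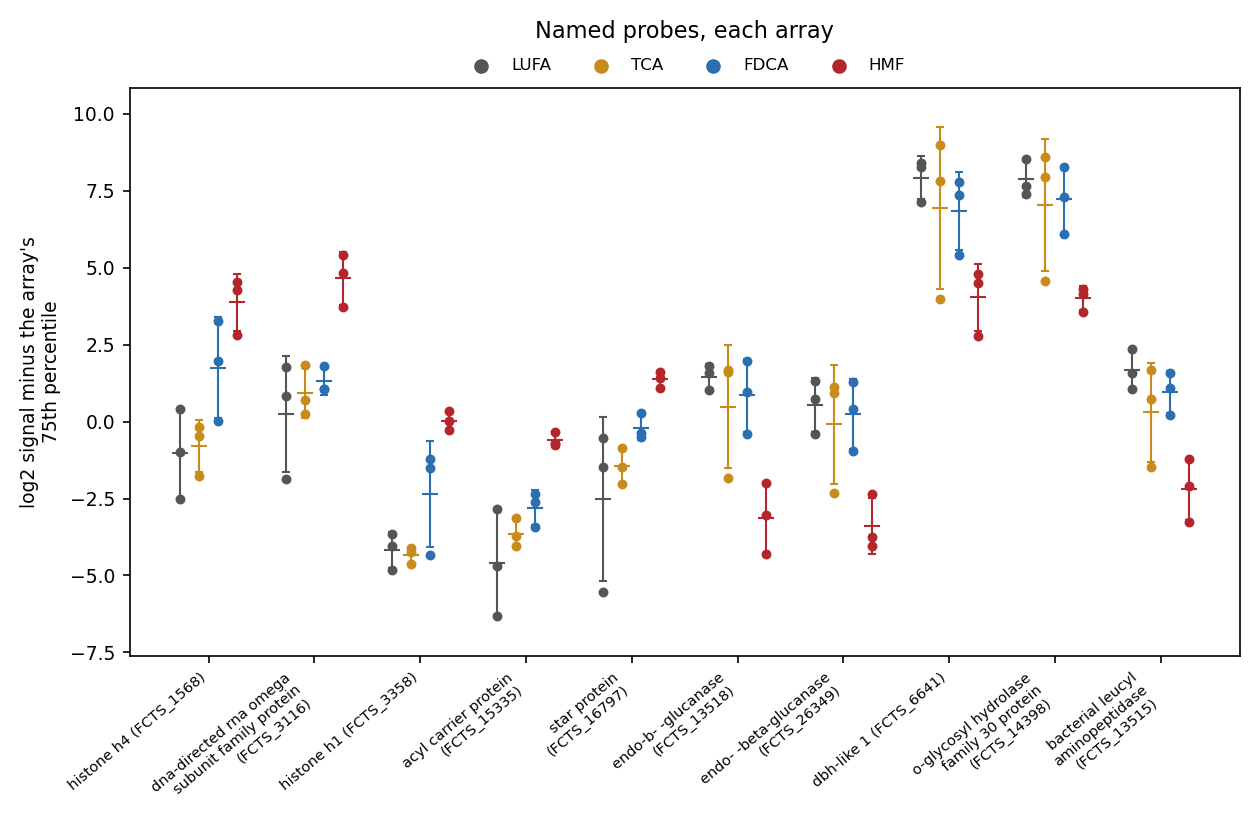
Each dot is 1 array of the group given by its colour, and the bars give the mean and SD of 3 arrays, for 10 probes named in the comparison of HMF with LUFA, as log2 signal relative to the array's 75th percentile. Histone H4 averaged 3.88 in HMF and -1.03 in LUFA, and endo-beta-glucanase FCTS_13518 averaged -3.12 and 1.46.

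In the DNA replication and cell cycle list 38 of 68 probes rose with HMF and 6 fell, or 45 and 6 when adjusted over the list alone. The list median was 1.21 (adjusted p = 7.56e-07 by limma's camera, adjusted p = 0.507 with an estimated correlation), and the medians on slides 1 and 3 were 0.88 and 1.92. The large subunit of replication factor C, which loads the clamp of DNA polymerase (FCTS_5523), rose by 2.13. A homolog of Cdc20, which activates the anaphase-promoting complex (FCTS_28384), was at least 1.96-fold higher, as no LUFA array was above background for it, and did not pass with normexp and the 75th percentile (adjusted p = 0.132). The DNA repair list had 14 of 33 probes higher and 4 lower, with the same counts when adjusted over the list alone. Its median was 0.66 (adjusted p = 0.00237, adjusted p = 0.507 with an estimated correlation), with 0.21 on slide 1 and 1.30 on slide 3, and it was 0.40 without LUFA 3 (adjusted p = 0.00546). The mismatch repair gene MSH6 (FCTS_6080) rose by 2.21, and a RAD54B-like gene of recombination (FCTS_5992) rose by 2.24. In the proteasome list 13 of 40 probes rose and 2 fell, with the same counts when adjusted over the list alone. Its median was 0.56 (adjusted p = 0.00193, adjusted p = 0.512 with an estimated correlation), with 0.58 and 0.75 on slides 1 and 3. Subunits alpha 3 (FCTS_3556) and alpha 5 (FCTS_1404) of the proteasome core rose by 1.37 and 1.05, and a probe for alpha 1 (FCTS_7789, above background on 1 of 3 HMF arrays) fell by 2.51, or by 1.88 without LUFA 3. The alpha 1 call ended with normexp and the 75th percentile (-0.56, adjusted p = 0.119), normexp and quantile (-0.50, adjusted p = 0.0911) and the authors' values (-0.65, adjusted p = 0.0835).

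In the muscle list 42 of 94 probes fell with HMF and 3 rose, or 51 and 4 when adjusted over the list alone. The list median was -1.01 (adjusted p = 8.33e-07, adjusted p = 0.507 with an estimated correlation), with -1.17 on slide 1 and -0.98 on slide 3. Probes for titin, the elastic giant protein of the sarcomere, fell (FCTS_11154, -1.84, and FCTS_23910, -2.02), and a myosin light chain (FCTS_2866) fell by 2.46. Genes of the nervous system followed, with 25 of 92 probes lower and 9 higher, or 27 and 10 when adjusted over the list alone. Their median was -0.64 (adjusted p = 0.00232, adjusted p = 0.313 with an estimated correlation), with -0.49 and -0.68 on slides 1 and 3. A glutamate receptor of the GLR-6 type (FCTS_14849, -1.69) and a GABA-gated chloride channel (FCTS_23402, -1.33) fell. Neither passed with normexp and the 75th percentile, where they were at -0.465 and -0.434 (adjusted p of 0.0634 and 0.057). A GABA receptor alpha-like probe (FCTS_29862) rose by 2.17. Ribosomal protein genes had 9 of 48 probes lower and 2 higher, or 4 and 1 when adjusted over the list alone. Their median was -0.55 (adjusted p = 0.00237, adjusted p = 0.627 with an estimated correlation), with -0.67 and -0.81 on slides 1 and 3. The ribosomal call ended with quantile normalisation, at -0.32 (adjusted p = 0.082). Ribosomal protein P0 (FCTS_5481) fell by 1.37, and protein L23 (FCTS_7310) fell by 1.11 without passing under quantile normalisation (adjusted p = 0.106).

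Of 121 probes for cytochrome P450s, which oxidise foreign and endogenous compounds, 32 fell with HMF and 3 rose, or 27 and 3 when adjusted over the list alone. Their median was -0.77 (adjusted p = 2.12e-06, adjusted p = 0.507 with an estimated correlation), with -0.58 and -1.02 on slides 1 and 3. The P450 probes FCTS_1297 (-1.84) and FCTS_8282 (-1.49) fell, and FCTS_2484 and a CYP2J2-like probe (FCTS_181) rose by 2.54 and 1.68. The aldehyde and alcohol metabolism list had 36 of 101 probes lower and 6 higher, or 42 and 7 when adjusted over the list alone. Its median was -0.80 (adjusted p = 0.000194, adjusted p = 0.507 with an estimated correlation), with -0.68 and -0.92 on slides 1 and 3. Aldehyde oxidases, which turn aldehydes into acids, fell (FCTS_10126, -2.38, FCTS_18860, -2.04, and FCTS_11034, -2.18). An alcohol dehydrogenase (FCTS_2056, above background on 1 of 3 LUFA arrays) rose by 2.09, but averaged over probes of its best hit the value was -0.051 (adjusted p = 0.886), and it did not pass with normexp and the 75th percentile (adjusted p = 0.0566).

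Conjugating enzymes, esterases and digestive enzymes gave weaker calls with HMF, each of which depended on single arrays. Phase II conjugation had 20 of 58 probes lower and 8 higher, or 22 and 10 when adjusted over the list alone, with a median of -0.66 (adjusted p = 0.0262, adjusted p = 0.624 with an estimated correlation). The median was -0.36 on slide 1 and -1.16 on slide 3, and the call ended without LUFA 3 (adjusted p = 0.172) and with the mean over probes of the same best hit (adjusted p = 0.0979). Glutathione S-transferase-like probes, which attach glutathione, fell (FCTS_16913, -2.28, and FCTS_6452, -1.46), and a UDP-glucuronosyltransferase (FCTS_18290) was at least 3.02-fold lower. Carboxylesterases and epoxide hydrolases had 15 of 66 probes lower and 5 higher, or 12 and 4 when adjusted over the list alone, with a median of -0.66 (adjusted p = 0.0168, adjusted p = 0.558 with an estimated correlation). The slide medians were -0.50 and -0.76, and this call too ended without LUFA 3 (adjusted p = 0.0971). Carboxylesterase-6 (FCTS_15695) fell by 2.03, and a juvenile hormone epoxide hydrolase (FCTS_6652) rose by 2.63. Esterase FE4 (FCTS_1637) rose by 2.16, but not with the mean over its best hit (0.67, adjusted p = 0.119). Digestive proteases and glycosidases had 39 of 203 probes lower and 14 higher, or 27 and 13 when adjusted over the list alone, with a median of -0.55 (adjusted p = 0.0432, adjusted p = 0.624 with an estimated correlation). The slide medians were -0.55 and -0.57, and the call ended without LUFA 1 (adjusted p = 0.0724), LUFA 3 (adjusted p = 0.104) or HMF 3 (adjusted p = 0.0885) and without a filter (adjusted p = 0.0707). A vitellogenic carboxypeptidase (FCTS_12790) fell by 2.26 and an aminopeptidase N-like probe (FCTS_22470) rose by 2.35, but not with the mean over its best hit (0.72, adjusted p = 0.131).

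All 11 of these lists also passed with slide as a block, and in each of the 11 every HMF array lay on 1 side of every LUFA array. With fry, a rotation test that allows for correlation within a list, 12 lists passed for HMF. Of the 11 called by camera, phase II conjugation (adjusted p = 0.0557), ribosomal proteins (adjusted p = 0.0988) and digestive enzymes (adjusted p = 0.13) did not pass with fry.

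The 11 other lists did not pass with camera for HMF. Each held called members, but 35.7% of all described probes were called, so called members alone do not mark a list response. With fry, 4 of them passed, which were heat shock proteins (adjusted p = 0.026), fatty acid metabolism (adjusted p = 0.026), antioxidant proteins (adjusted p = 0.0449) and haemolymph proteins (adjusted p = 0.0449). Fatty acid and lipid metabolism had 39 of 186 probes lower and 17 higher (34 and 13 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.0716). It passed with slide as a block (adjusted p = 0.0398), without LUFA 2 (adjusted p = 0.0335), with normexp and quantile or the authors' values (adjusted p = 0.0434 in both), with the filter on all 12 arrays (adjusted p = 0.0213) and with only both groups in the fit (adjusted p = 0.0361). A delta desaturase, which inserts double bonds into fatty acids (FCTS_23599), rose by 2.54, and a sterol desaturase (FCTS_2546) fell by 1.95. Heat shock proteins and chaperones had 14 of 56 probes higher and 10 lower (15 and 10 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.224). An activator of the HSP90 ATPase (FCTS_1570) rose by 2.03 and a chaperone protein (FCTS_26346) fell by 2.40. Antioxidant and metal-binding proteins had 10 of 27 probes higher and 2 lower, the same counts when adjusted over the list alone, and a median of 0.23 (adjusted p = 0.166), which was -0.024 without a filter. Peroxiredoxin, which removes peroxides (FCTS_13396), rose by 1.58 and manganese superoxide dismutase (FCTS_6721) by 1.33. Drug and organic solute transporters went both ways, with 22 of 159 probes higher and 17 lower (19 and 15 adjusted over the list alone) and a median of -0.24 (adjusted p = 0.702). A multidrug resistance-associated protein (FCTS_9403) rose by 1.89 and an organic cation transporter (FCTS_11441) fell by 1.55.

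Cuticle and moulting had 13 of 116 probes higher and 12 lower with HMF (10 and 8 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.429). A pupal cuticle protein (FCTS_24775) rose by 3.44, and chitin deacetylase 4 (FCTS_2773) and chitinase 1 (FCTS_13781), which modify and cleave chitin, rose by 2.07 and 1.89. Vitellogenesis and oogenesis had 5 of 34 probes lower and 3 higher, the same counts when adjusted over the list alone, with a median of -0.48 (adjusted p = 0.375). The yolk precursor vitellogenin 2 (FCTS_1441) fell by 1.81, and probes for the germ-line helicase vasa rose by 1.51 (FCTS_11638) and 2.01 (FCTS_111, 1.39 without LUFA 3). Immune recognition had 4 of 38 probes in each direction, also when adjusted over the list alone, with a median of -0.078 (adjusted p = 0.747), and a peptidoglycan recognition protein (FCTS_14263) fell by 2.15. In the beta-lactam list 1 of 19 probes fell and 0 rose, also when adjusted over the list alone, with a median of -0.12 (adjusted p = 0.582). The called member is described as a beta-lactamase domain protein (FCTS_2764), which is not a biosynthetic enzyme, and its call ended with the mean over its best hit (-0.20, adjusted p = 0.854). The mitochondrial respiratory chain had 3 of 45 probes higher and 1 lower (0 and 0 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.319), and an ATP synthase subunit s-like probe (FCTS_6052) rose by 1.31, a call that ended without HMF 2 (adjusted p = 0.0551) or HMF 3 (adjusted p = 0.0523). Haemolymph and storage proteins had 2 of 16 probes lower and 1 higher, also when adjusted over the list alone, with a median of -0.80 (adjusted p = 0.183). The list passed with the filter on all 12 arrays (-0.81, adjusted p = 0.0441). The oxygen carrier hemocyanin subunit 6 (FCTS_32016, above background on 1 of 3 HMF arrays) fell by 2.90. Of 19 probes with a best hit in the bacterium Wolbachia 2 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.206).

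**Figure D3:**
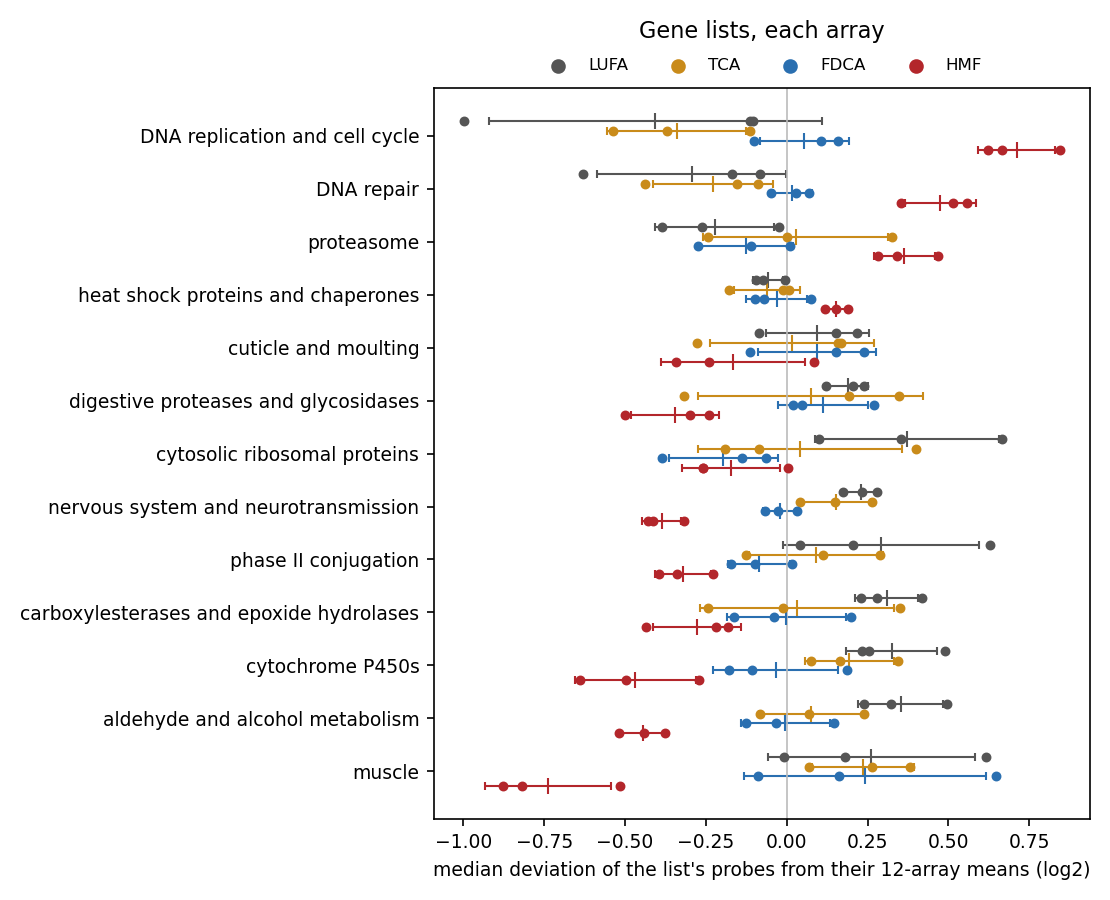
Each dot is 1 array, coloured by group, and gives the median log2 deviation of a list's probes from their mean over the 12 arrays, with a tick at the group mean and a bar for the SD of 3 arrays. The list score of DNA replication and cell cycle was 1.12 higher in HMF than in LUFA (0.57 to 1.67), and that of muscle was lower, with an interval of -1.52 to -0.48.

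The comparison of FDCA with LUFA asks which genes respond to the furan that carries a pair of carboxylic acid groups, the compound named in the series title. No single gene changed beyond the test's threshold. As groups, genes for ribosomal proteins and for enzymes that process foreign compounds were lower relative to other genes, and genes for DNA copying were higher, but 0 of these list calls held with an estimated correlation. The ribosomal median was -0.0090 with quantile normalisation, and the call for DNA copying ended without LUFA 3. In limma's test 0 of 27749 probes passed, with 4018 at an unadjusted p under 0.05 against 1387 expected by chance and a smallest adjusted p of 0.0934. With slide as a block 1 probe passed, an unknown product (FCTS_4745) that was 3.02 higher (adjusted p = 0.0435), named after its value was seen. The groups did not overlap for 19.7% of the probes, against 10% by chance. The median over all probes was 0.12.

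Of the described genes, those with the smallest p for FDCA all had an adjusted p of 0.273 and did not pass, nor did they with slide as a block (adjusted p = 0.471). Higher values were found for cytochrome b, a subunit of mitochondrial complex III (FCTS_2907, 1.99), the WD repeat protein 61 (FCTS_2124, 1.30), adenosine kinase 2, which phosphorylates adenosine (FCTS_732, 1.47), and a zinc finger protein (FCTS_21841, at least 1.97-fold higher). A C4b-binding protein probe (FCTS_2420) was above background on no array of either group. Lower values were found for globin 1, which binds oxygen (FCTS_191, -1.76), a trehalose transporter (FCTS_6187, -1.69), a nitrilase (FCTS_711, -2.16), arginase, which splits arginine (FCTS_21535, -2.40), and a UDP-glucuronosyltransferase (FCTS_18290, at least 1.80-fold lower). Globin 1 averaged 2.56 ± 0.46 (SD, n = 3) in FDCA and 4.31 ± 0.49 (SD, n = 3) in LUFA.

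Camera passed 9 of 22 lists for FDCA, 1 higher and 8 lower, all 9 also with slide as a block and 0 with an estimated correlation. Ribosomal protein genes had a median of -0.56 (adjusted p = 1.95e-08, adjusted p = 0.507 with an estimated correlation), with -0.41 and -0.40 on slides 1 and 2. The ribosomal call ended with quantile normalisation (-0.0090, adjusted p = 0.98), normexp with quantile (-0.0098, adjusted p = 0.998) and the authors' values (-0.021, adjusted p = 0.84). Genes of the mitochondrial respiratory chain had a median of -0.29 (adjusted p = 4.37e-05, adjusted p = 0.507 with an estimated correlation), and this call ended under the same settings, with adjusted p of 0.532, 0.511 and 0.31. P450s had a median of -0.39 (adjusted p = 1.94e-07, adjusted p = 0.507 with an estimated correlation), with -0.058 and -0.41 on slides 1 and 2. Aldehyde and alcohol metabolism had -0.34 (adjusted p = 3.06e-06, adjusted p = 0.507 with an estimated correlation), with -0.051 and -0.39 on slides 1 and 2. Phase II conjugation had -0.45 (adjusted p = 1.14e-05, adjusted p = 0.507 with an estimated correlation), with -0.13 and -0.44 on slides 1 and 2. Carboxylesterases and epoxide hydrolases had -0.30 (adjusted p = 0.000685, adjusted p = 0.507 with an estimated correlation), with -0.0066 and -0.36 on slides 1 and 2.

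DNA replication and cell cycle genes had a median of 0.46 for FDCA (adjusted p = 0.00322, adjusted p = 0.624 with an estimated correlation), with 0.23 and 0.15 on slides 1 and 2. This call ended without LUFA 3, at 0.21 (adjusted p = 0.106). The replication helicase subunits MCM3 (FCTS_8374, 1.61) and MCM7 (FCTS_27904, 1.33) and histone H4 (FCTS_1568, 2.78) were higher without passing, with adjusted p of 0.282, 0.312 and 0.312. Nervous system genes had a median of -0.19 (adjusted p = 0.000568, adjusted p = 0.313 with an estimated correlation), and were the only list that passed with fry (adjusted p = 0.0317). Their array-level difference was -0.25 (-0.39 to -0.11). Fatty acid and lipid metabolism had a median of -0.12 (adjusted p = 0.00589, adjusted p = 0.507 with an estimated correlation), which was -0.22 without LUFA 2 and -0.20 without FDCA 3. With normexp and the 75th percentile the medians of the nervous system and of fatty acid metabolism were 0.011 and 0.018, where the median over all probes was 0.20, so both stayed below it. The call of fatty acid metabolism ended with the authors' values (adjusted p = 0.0561). Members called over all probes numbered 0 in every list, and adjusted over the list alone 1 probe of phase II conjugation rose, 2 fell and 0 of the other lists did. The 13 other lists did not pass, with adjusted p from 0.128 for digestive enzymes to 0.97 for the proteasome. Of these, muscle passed without FDCA 1 (-0.17, adjusted p = 0.00202), LUFA 2 (-0.078, adjusted p = 0.0299) or LUFA 3 (-0.18, adjusted p = 0.0228), and digestive enzymes passed without LUFA 2 (-0.061, adjusted p = 0.0423). With normexp and the 75th percentile muscle (-0.041, adjusted p = 0.0016), digestive enzymes (0.052, adjusted p = 0.017) and cuticle and moulting (0.054, adjusted p = 0.041) passed. These medians too lay below the 0.20 over all probes in that setting, so none of them is a rise relative to the other probes. Without a filter muscle (0.0084, adjusted p = 0.0393) and digestive enzymes (-0.023, adjusted p = 0.0322) passed. Camera compares a list with the other probes, so the sign of these medians near 0 does not give its direction. Digestive enzymes also passed with only both groups in the fit (adjusted p = 0.0385), and haemolymph proteins with the filter on all 12 arrays (-0.34, adjusted p = 0.0356).

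The comparison of TCA with LUFA asks which genes respond to the treatment labelled TCA. No gene passed. Fewer genes than chance gives had a small p, and slightly more did with slide as a block. Ribosomal protein genes and genes that process foreign compounds were slightly lower as groups, but not on every slide, and 0 of these list calls held with an estimated correlation. The ribosomal median was above 0 with quantile normalisation, normexp with quantile and the authors' values. In limma's test 0 of 27725 probes passed, with 1110 at an unadjusted p under 0.05 against 1386 expected by chance, and the smallest adjusted p was 0.777. With slide as a block the count was also 0, with 1506 at an unadjusted p under 0.05 against 1386 expected by chance. The groups did not overlap for 6.61% of the probes, against 10% by chance. The median over all probes was 0.087.

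The described genes with the smallest p for TCA did not pass, with adjusted p from 0.777 to 0.979. A metalloproteinase of the ADAMTS family, which cleaves extracellular matrix (FCTS_16643), was lower, at -2.52 (-3.41 to -1.62, adjusted p = 0.777), with -2.39, -2.08 and -3.08 on slides 1 to 3. A solute-binding protein (FCTS_21521, -1.73), a tail fiber domain protein (FCTS_27268, -2.08), a nitrilase (FCTS_711, -1.69) and a protein like the matrix protein ig-h3 (FCTS_34127, -1.44) were also lower. Among higher values were a glutathione S-transferase (FCTS_962, 0.94), a peroxidasin homolog (FCTS_24723, at least 3.39-fold), an acetylglucosaminyltransferase (FCTS_32615, at least 1.67-fold), UBR4, a ubiquitin ligase (FCTS_4596, at least 1.13-fold) and casein kinase I alpha (FCTS_743, at least 1.01-fold).

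Camera passed 8 of 22 lists for TCA, 1 higher and 7 lower, all 8 also with slide as a block, and 0 with an estimated correlation or with fry. In all 7 lists called lower the median was above 0 on slide 1. Ribosomal protein genes had a median of -0.29 (adjusted p = 1.46e-06, adjusted p = 0.533 with an estimated correlation), with 0.12, -0.34 and -0.70 on slides 1 to 3. The median was -0.46 without TCA 1 and -0.16 without TCA 2. This call ended without LUFA 3, at -0.17 (adjusted p = 0.106), and the sign turned with quantile normalisation, normexp with quantile and the authors' values, at 0.0042, 0.0078 and 0.0035. Aldehyde and alcohol metabolism had -0.23 (adjusted p = 1.83e-05, adjusted p = 0.507 with an estimated correlation), with 0.017, -0.28 and -0.34 on slides 1 to 3, and -0.15 without TCA 2. Carboxylesterases and epoxide hydrolases had -0.13 (adjusted p = 0.000743, adjusted p = 0.507 with an estimated correlation), with -0.35 without TCA 1, and the call ended without TCA 2, at -0.031 (adjusted p = 0.0533), or LUFA 3 (adjusted p = 0.184). P450s had -0.092 (adjusted p = 0.0026, adjusted p = 0.533 with an estimated correlation), with -0.14 without TCA 1 and -0.16 without TCA 2, and the call ended without LUFA 3 (adjusted p = 0.367) or TCA 3, at -0.055 (adjusted p = 0.0732). Phase II conjugation had -0.22 (adjusted p = 0.00326, adjusted p = 0.556 with an estimated correlation), and the call ended without TCA 2, at -0.11 (adjusted p = 0.149), or LUFA 3, at -0.027 (adjusted p = 0.933), and with quantile normalisation (adjusted p = 0.151), normexp with quantile (adjusted p = 0.0636) or the authors' values (adjusted p = 0.0706).

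Genes of the mitochondrial respiratory chain had a median of -0.083 for TCA (adjusted p = 0.0147, adjusted p = 0.624 with an estimated correlation), with 0.33, -0.24 and -0.36 on slides 1 to 3. The call ended without TCA 2 (adjusted p = 0.243), TCA 3 (adjusted p = 0.0845) or LUFA 3 (adjusted p = 0.947), and the sign turned with quantile normalisation (0.025), normexp with quantile (0.018) and without LUFA 3 (0.024). It also ended without a filter (adjusted p = 0.0701) and with the authors' values (adjusted p = 0.98), and the median was -0.23 without LUFA 1 and -0.19 without TCA 1. Digestive enzymes had -0.018 (adjusted p = 0.0342, adjusted p = 0.624 with an estimated correlation), and the call ended without LUFA 1, at -0.045 (adjusted p = 0.155), LUFA 3, at -0.16 (adjusted p = 0.237), or TCA 2, where the median was 0.13 (adjusted p = 0.916). It also ended with quantile normalisation (adjusted p = 0.191), the array median (adjusted p = 0.0796), normexp and quantile (adjusted p = 0.186), the authors' values (adjusted p = 0.204) and only both groups in the fit (adjusted p = 0.0972). Their median was 0.047 with normexp and the 75th percentile, below the median of 0.070 over all probes in that setting. It was -0.13 without TCA 1, -0.070 without LUFA 2 and -0.067 without TCA 3. Proteasome genes had 0.26 (adjusted p = 0.0247, adjusted p = 0.607 with an estimated correlation), with 0.18, 0.58 and 0.016 on slides 1 to 3, and the call ended without TCA 1 (adjusted p = 0.138), TCA 2, at 0.17 (adjusted p = 0.567), or LUFA 2 (adjusted p = 0.289), without a filter (adjusted p = 0.0576) and with only both groups in the fit (adjusted p = 0.0708), and the median was 0.41 without TCA 3. Members called numbered 0 in every list, and 0 when adjusted over the list alone. The 14 other lists did not pass. Some of them passed lower without single arrays, which were DNA replication without LUFA 3 (-0.22, adjusted p = 0.000429) or TCA 3 (-0.12, adjusted p = 0.0414), vitellogenesis without TCA 1 (-0.33, adjusted p = 0.0123) or LUFA 2 (-0.27, adjusted p = 0.013), and cuticle and moulting without LUFA 2 (-0.14, adjusted p = 0.0123) or TCA 3 (-0.094, adjusted p = 0.0427). Muscle passed lower without TCA 2 (-0.037, adjusted p = 0.0176) or LUFA 2 (-0.046, adjusted p = 0.0362), and fatty acid metabolism without LUFA 2 (-0.037, adjusted p = 0.038). Vitellogenesis also passed with normexp and the 75th percentile (-0.065, adjusted p = 0.0422), and genes with Wolbachia hits passed with the filter on all 12 arrays (0.23, adjusted p = 0.0244).

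The comparison of HMF with FDCA sets the related furans side by side. Camera called muscle genes lower with HMF than with FDCA, and genes for DNA copying, DNA repair and the proteasome higher, with adjusted p of 0.507, 0.533, 0.507 and 0.507 with an estimated correlation. In these lists 33 of 94, 17 of 68, 7 of 33 and 10 of 40 probes passed in that direction. Ribosomal protein genes did not differ detectably. The calls for single genes did not hold with slide as a fixed block, and most held with slide as a random block. The random block used an estimated correlation of 0.0784 within slides, so its fit stayed close to that without a block. In limma's test 4415 of 27738 probes passed, 2402 higher with HMF and 2013 lower, and 3718 differed at least 2-fold. With slide as a fixed block 0 passed, the smallest adjusted p was 0.0645 and 8285 probes had an unadjusted p under 0.05. With slide as a random block 4265 passed, 2334 higher and 1931 lower, and 4109 of the 4415 were among them in the same direction. The log2 differences without a block and with the fixed block correlated at r of 0.987 across probes, and the median standard error was 0.314 without and 0.367 with that block. The count was 0 without FDCA 1, FDCA 2, HMF 2 or HMF 3, 2870 without HMF 1 and 2932 without FDCA 3. With quantile normalisation it was 2316. The share of called probes that were higher was 54.4%, and it was 71.9% with the array median, 66.2% with normexp and quantile and 66.0% with the authors' values. The median over all probes was -0.21, and these 3 settings moved it by 0.15, 0.19 and 0.19. The groups did not overlap for 46.6% of the probes, against 10% by chance.

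Between these furans, synaptotagmin 1, a calcium sensor of vesicle release (FCTS_29358), was 4.53 higher with HMF (95% interval 2.07 to 6.99, adjusted p = 0.0322), and 4.66 on slide 1. Pumilio 2, a repressor of messenger RNA in germ cells (FCTS_6182), was 2.90 higher (1.79 to 4.01, adjusted p = 0.0177), and 2.88 on slide 1. Noggin 2, an inhibitor of BMP signals (FCTS_20800), was 2.75 higher (1.88 to 3.62), and chromobox protein 5, which binds silent chromatin (FCTS_11654), was 2.63 higher. The omega subunit probe (FCTS_3116) was 3.35 higher, and 0.056 averaged over its best hit (adjusted p = 0.95). The endo-beta-glucanases FCTS_13518 and FCTS_26349 were lower, at -3.97 (-5.98 to -1.95, adjusted p = 0.0237) and -3.63 (adjusted p = 0.0272), with -3.98 and -3.64 on slide 1. Chitin-binding proteins (FCTS_22146, -3.46, and FCTS_10000, -3.15) and the family 30 glycosyl hydrolase (FCTS_14398, -3.22) were lower too. With slide as a fixed block the adjusted p of these 10 lay between 0.0645 and 0.0765, and without FDCA 1, FDCA 2, HMF 2 or HMF 3 none of them passed. The synaptotagmin 1 call also ended with quantile normalisation (adjusted p = 0.0525) and normexp and quantile (adjusted p = 0.0546). Normexp and quantile and the authors' values ended those of FCTS_26349 (-2.22 and -2.50, adjusted p of 0.0721 and 0.0551) and FCTS_22146 (-1.91 and -2.22, adjusted p of 0.0643 and 0.0556). That of FCTS_14398 ended without HMF 1 (adjusted p = 0.0573) and with the mean over its best hit (-2.27, adjusted p = 0.074). Without single arrays synaptotagmin 1 lay between 3.57 and 5.43 and FCTS_13518 between -4.59 and -3.37, and without FDCA 3 FCTS_26349 was at -4.23 and FCTS_22146 at -4.19.

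Among lists, the array-level muscle score was lower with HMF than with FDCA, at -0.98 (-1.50 to -0.46), with 33 of 94 probes lower and 3 higher, or 47 and 3 when adjusted over the list alone. The muscle median was -0.97 (adjusted p = 5.82e-07, adjusted p = 0.507 with an estimated correlation), and -1.18 on slide 1. DNA replication differed by 0.66 (0.11 to 1.21), with 17 of 68 probes higher and 3 lower (28 and 4 adjusted over the list alone) and an adjusted p of 1.92e-05 (adjusted p = 0.533 with an estimated correlation). Proteasome genes had a median of 0.59 (adjusted p = 0.000241, adjusted p = 0.507 with an estimated correlation), and DNA repair had 0.19 (adjusted p = 0.00344, adjusted p = 0.507 with an estimated correlation). Antioxidant genes had 0.37 (adjusted p = 0.033, adjusted p = 0.507 with an estimated correlation), with 0.37 on slide 1. P450s differed by -0.43 (-0.75 to -0.12, adjusted p = 0.0354, adjusted p = 0.624 with an estimated correlation), and genes with Wolbachia hits by -0.47 (-0.79 to -0.15, adjusted p = 0.00855, adjusted p = 0.507 with an estimated correlation). All 7 of these lists passed with slide as a block. Aldehyde and alcohol metabolism (adjusted p = 0.0073), digestive enzymes (adjusted p = 0.00866) and heat shock proteins (adjusted p = 0.0421) passed with the block alone. The scores of ribosomal proteins (0.024, -0.43 to 0.48) and phase II conjugation (-0.24, -0.60 to 0.13) had intervals that held 0. Doses were not given in the sources used here, so a difference in compound and one in dose cannot be told apart.

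The comparison of HMF with TCA tests directly whether those treatments differed. Probes for histones H4 and H1 were higher with HMF. Camera called replication genes higher and muscle genes and P450s lower, as against LUFA, each with adjusted p = 0.507 with an estimated correlation. In these lists 35 of 68, 39 of 94 and 23 of 121 probes passed in that direction. In limma's test 7104 of 27719 probes passed, 3934 higher and 3170 lower, and 5768 differed at least 2-fold. A block for slide gave 6677, 3743 higher and 2934 lower. The count was 3817 without TCA 2, 3124 without HMF 2 and 2278 without HMF 3. Of the called probes 55.4% were higher, and 68.5% with the array median, which moved the median over all probes by 0.11 from -0.25. The groups did not overlap for 49.1% of the probes, against 10% by chance. Histone H4 (FCTS_1568) was 4.68 higher (2.73 to 6.63, adjusted p = 0.00779), histone H1 (FCTS_3358) was 4.36 higher (2.90 to 5.82, adjusted p = 0.00726), a myeloperoxidase probe (FCTS_15516) 3.81 and the pupal cuticle protein (FCTS_24775) 3.56. The omega subunit probe (FCTS_3116) was 3.72 higher, and -0.42 averaged over its best hit. A probable lanosterol demethylase, an enzyme of sterol synthesis (FCTS_8767), was lower, at -3.93 (adjusted p = 0.0181). Its call ended with the mean over its best hit (adjusted p = 0.101), with normexp and quantile (adjusted p = 0.0542), with only both groups in the fit (adjusted p = 0.0553) and without TCA 2 (adjusted p = 0.0575) or HMF 3 (adjusted p = 0.0678). Caffeoyl O-methyltransferase (FCTS_28139, -3.75), a SEC14-like lipid transfer protein (FCTS_20197, -3.35) and the endo-beta-glucanases FCTS_13518 (-3.60) and FCTS_26349 (-3.29) were lower too. The SEC14-like probe was above background on 1 of 3 HMF arrays and FCTS_8767 on 2 of 3, and the pupal cuticle probe was above background on 1 of 3 TCA arrays and FCTS_15516 on 2 of 3, so these sizes rest in part on signals near background. The SEC14-like call ended with the authors' values, where the difference was -0.73 (adjusted p = 0.0527). The calls of both glucanases ended without TCA 1 (adjusted p of 0.056 and 0.0739), TCA 3 (0.0592 and 0.075), HMF 2 (0.0535 and 0.0752) or HMF 3 (0.0771 and 0.0878). The call of FCTS_26349 also ended with normexp and quantile (adjusted p = 0.0741) and with the authors' values (adjusted p = 0.0543). With slide as a block all 10 passed, with adjusted p between 0.0187 and 0.045. Without single arrays FCTS_8767 lay between -4.80 and -2.86, FCTS_13518 between -4.76 and -3.00, FCTS_26349 between -4.41 and -2.67 and FCTS_20197 between -4.11 and -2.67, and FCTS_15516 was at 3.11 without TCA 2.

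Camera passed 8 of 22 lists between HMF and TCA, 3 higher and 5 lower, all 8 also with slide as a block and 0 with an estimated correlation. DNA replication had 35 of 68 probes higher and 4 lower (41 and 5 adjusted over the list alone), with a median of 1.16 (adjusted p = 1.95e-08, adjusted p = 0.507 with an estimated correlation) and 1.12 and 0.90 on slides 1 and 3. Muscle had 39 of 94 probes lower and 2 higher (53 and 2 adjusted over the list alone), with a median of -1.07 (adjusted p = 7.61e-07, adjusted p = 0.507 with an estimated correlation) and -0.93 and -0.95 on slides 1 and 3. DNA repair had a median of 0.81 (adjusted p = 0.000266, adjusted p = 0.507 with an estimated correlation) and proteasome genes had 0.47 (adjusted p = 0.0157, adjusted p = 0.567 with an estimated correlation). P450s had a median of -0.65 (adjusted p = 0.000173, adjusted p = 0.507 with an estimated correlation), and nervous system genes had -0.66 (adjusted p = 0.00397, adjusted p = 0.335 with an estimated correlation). Aldehyde and alcohol metabolism had -0.60 (adjusted p = 0.0156, adjusted p = 0.558 with an estimated correlation), and genes with Wolbachia hits had -0.59 (adjusted p = 0.0233, adjusted p = 0.533 with an estimated correlation). Ribosomal proteins (-0.30) passed with the block alone (adjusted p = 0.0468).

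The comparison of FDCA with TCA found no called gene. Camera called DNA replication genes slightly higher with FDCA as a group and P450s slightly lower, both with an adjusted p of 0.507 with an estimated correlation. The array-level differences of 0.40 (-0.16 to 0.95) and -0.23 (-0.54 to 0.086) had intervals that held 0. In limma's test 0 of 27734 probes passed, with 1702 at an unadjusted p under 0.05 against 1387 expected by chance, a smallest adjusted p of 0.712, and 0 with slide as a block. The groups did not overlap for 17.2% of the probes, against 10% by chance. The smallest p belonged to tumor susceptibility gene 101, an endosomal sorting protein (FCTS_6640, at least 1.44-fold higher), a C4b-binding protein probe above background on no array of either group (FCTS_2420), a prostatic acid phosphatase-like probe (FCTS_27918, 1.38, above background on 1 of 3 TCA arrays), the splicing factor SPF27 (FCTS_7098, at least 1.52-fold higher) and a protein phosphatase 2A subunit (FCTS_2323, 1.48). On the lower side stood caffeoyl O-methyltransferase (FCTS_28139, -2.46), nucleoside diphosphate kinase (FCTS_18177, at least 1.76-fold lower), a CRAL-TRIO protein (FCTS_12665, -1.14), twist2 (FCTS_17998, above background on no FDCA array and too dim with TCA for a lower bound above 1) and a spherulin 4-like protein (FCTS_11784, -1.57). Their adjusted p lay between 0.712 and 0.761. Camera passed 8 lists, of which 3 also passed with slide as a block and 0 with an estimated correlation. These 3 were DNA replication (0.50, adjusted p = 2.9e-06, adjusted p = 0.507 with an estimated correlation), P450s (-0.22, adjusted p = 0.000108, adjusted p = 0.507 with an estimated correlation) and the nervous system (-0.16, adjusted p = 0.00121, adjusted p = 0.313 with an estimated correlation). Ribosomal proteins (-0.24), phase II conjugation (-0.20), the respiratory chain (-0.19), fatty acid metabolism (-0.087) and DNA repair (0.22) passed without the block alone, and proteasome genes (-0.20) with the block alone (adjusted p = 0.00366).

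The responses to the 3 treatments were compared through their log2 differences from LUFA over 26931 complete probes. These differences share the LUFA arrays, so 100 simulations of unchanged groups were run for comparison. The highest simulated r was 0.945 for TCA and HMF, 0.948 for TCA and FDCA, and 1 for HMF and FDCA. Unchanged groups were thus nearly alike in some draws, so the simulated values do not give the level that sharing alone produces. HMF and FDCA correlated at r of 0.631 across probes, against a simulated mean of 0.465, and 5 of 100 simulations had a covariance as large. TCA and FDCA correlated at 0.638 (simulated mean 0.487, 31 of 100 as large) and TCA and HMF at 0.449 (simulated mean 0.493, 26 of 100 as large). Probes are not independent replicates. With 3 controls, LUFA could not be split to keep 2 arrays on each side.

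A median over lists can hide members that move apart. The median, the mean and the camera test differed in sign for 26 combinations of list and comparison, 0 of them among those that passed. Transporters with FDCA, for example, had a median of 0.0095 while camera pointed lower (adjusted p = 0.275).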

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

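Leaving out probes with adapter sequence, widening the list patterns to further spellings and leaving out single arrays for the added lists were the alternatives chosen only after the data were seen. The cause of the changes given here was not tested. The HMF against LUFA count lay between 5450 and 9143 when single arrays were left out and between 7248 and 10201 under the other alternatives. Quantile normalisation kept 8059 of its calls in the same direction, the array median 8858, the authors' values 7848 and the slide block 8687, with 0 in the opposite direction. The HMF against TCA count lay between 2278 and 5844 without single arrays and between 5976 and 7795 otherwise. The HMF against FDCA count depended on both slide and arrays, with 0 to 2932 without single arrays and 0 to 6338 under the other alternatives, among them 0 with slide as a fixed block, 4265 with slide as a random block, 2316 with quantile normalisation and 6338 with normexp and the 75th percentile. The fixed block left the size of the differences nearly unchanged (median 1.28 without and 1.24 with it) and raised their standard error from 0.314 to 0.367. The FDCA against LUFA count was 1 with slide as a fixed block and 0 under every other alternative, and those of TCA against LUFA and FDCA against TCA were 0 under all of them. Over the comparisons with LUFA 28 list calls were made, with 20 to 34 without single LUFA arrays and 21 to 32 otherwise. Without LUFA 3, 18 of these 28 kept their call, and with slide as a fixed block all 28 did. Of 119 passing pairs of a named gene and a comparison, 105 kept their call with the slide block, 102 with the mean over probes of the same best hit, and 95 without HMF 3.

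Scaling moved the median over all probes by more than 0.1 for HMF against FDCA and HMF against TCA, by 0.15 and 0.12 with quantile normalisation, 0.15 and 0.11 with the array median, 0.19 and 0.20 with normexp and quantile, and 0.19 and 0.20 with the authors' values. For FDCA against LUFA it moved by -0.12 with the array median, -0.11 with normexp and quantile and -0.11 with the authors' values. No list called for HMF against LUFA changed its direction under any scaling.

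Some values changed sign. Camera tests a list against the other probes, so a list median that crosses 0 need not turn the tested direction. With the mean over probes of the same best hit FCTS_3116 was at -0.42 for HMF against TCA and FCTS_2056 at -0.051 for HMF against LUFA. For TCA against LUFA, quantile normalisation put the respiratory chain at 0.025 and ribosomal proteins at 0.0042, normexp with quantile put them at 0.018 and 0.0078, the authors' values put ribosomal proteins at 0.0035, and normexp with the 75th percentile put digestive enzymes at 0.047. The medians over all probes in these settings were 0.020, 0.0058, -0.0013 and 0.070, in that order. Ribosomal proteins with quantile normalisation and digestive enzymes thus stayed below that median, and the other values lay above it. Without single arrays the TCA medians ranged from -0.14 to 0.17 for cuticle and moulting, -0.16 to 0.13 for digestive enzymes, -0.23 to 0.024 for the respiratory chain, -0.22 to 0.19 for DNA replication and -0.089 to 0.12 for muscle. For FDCA against LUFA, normexp with the 75th percentile put cuticle and moulting at 0.054, digestive enzymes at 0.052, fatty acid metabolism at 0.018 and the nervous system at 0.011, no filter put muscle at 0.0084, and the widened pattern put transporters at -0.036. The median over all probes was 0.20 for FDCA with normexp and the 75th percentile, so the lists named for that setting stayed below it. List results that did not pass came to pass in the same direction 8 times without 1 array and 13 times under another alternative. Each list in each alternative was counted here, so 1 list can count more than once. Signal over background limits the dim probes, since 21022 of the 27795 kept probes were well above background on all 12 arrays.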

Other observations

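The lists of germ-line genes, zinc finger proteins and cell wall hydrolases, the widened patterns, and the tests of LUFA 3, of germ-line RNA, of shared LUFA arrays and of adapter sequence were chosen only after the result was seen, and the tests of probe trend, of slide and of other splits were set before.

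Of 40 probes for germ-line and small RNA pathway genes, such as vasa and pumilio, 21 rose and 2 fell with HMF against LUFA, or 25 and 3 when adjusted over the list alone. Their median was 1.26 (adjusted p = 3.44e-07 by camera in limma, adjusted p = 0.326 with an estimated correlation), with 0.64 on slide 1 and 1.79 on slide 3, and 3 of the 40 were also in a fixed list. The same list had a median of 0.39 for FDCA (adjusted p = 0.0249, adjusted p = 0.526 with an estimated correlation, 0.045 and 0.27 on slides 1 and 2) and 0.085 for TCA (adjusted p = 0.786), or -0.093 without LUFA 3. The FDCA call ended without LUFA 3, at 0.21 (adjusted p = 0.187), or FDCA 3 (adjusted p = 0.0731). Zinc finger proteins, a large family of DNA- and RNA-binding factors, rose in 258 of 486 probes with HMF and fell in 20, or 283 and 26 when adjusted over the list alone. Their median was 1.02 (adjusted p = 8.68e-16, adjusted p = 0.326 with an estimated correlation), with 0.81 and 1.40 on slides 1 and 3. It was 0.40 for FDCA (adjusted p = 1.31e-05, adjusted p = 0.516 with an estimated correlation, 0.22 without LUFA 3) and 0.098 for TCA (adjusted p = 0.769), where the list passed higher without TCA 2 (0.19, adjusted p = 0.0308) and lower without LUFA 3 (-0.094, adjusted p = 0.0294). Cell wall hydrolases fell in 18 of 63 probes with HMF and rose in 5, or 20 and 5 when adjusted over the list alone. Their median was -0.85 (adjusted p = 0.000821, adjusted p = 0.516 with an estimated correlation), with -0.72 and -1.18 on slides 1 and 3, and 48 of the 63 were also in a fixed list. It was -0.14 for FDCA (adjusted p = 0.127, but -0.33 with adjusted p = 0.0407 without FDCA 1, and -0.0069 without FDCA 3) and -0.31 for TCA (adjusted p = 0.000365, adjusted p = 0.516 with an estimated correlation), where slide 1 gave 0.32. The TCA value turned to 0.17 without TCA 2 (adjusted p = 0.888), was -0.52 without TCA 1 and -0.19 without LUFA 2, and lost its call without LUFA 3 (adjusted p = 0.07). With further spellings, 25 of 93 phase II probes fell with HMF and 14 rose, with a median of -0.50 (adjusted p = 0.0299, adjusted p = 0.516 with an estimated correlation), with a call that ended without LUFA 3 (adjusted p = 0.187), and 25 of 187 transporter probes fell and 22 rose, with a median of -0.35 (adjusted p = 0.19). For FDCA these widened lists were at -0.42 (adjusted p = 6.64e-07, adjusted p = 0.326 with an estimated correlation) and -0.036 (adjusted p = 0.0338, adjusted p = 0.452 with an estimated correlation). The transporter call ended without LUFA 1 (-0.081, adjusted p = 0.137) or FDCA 2 (0.0097, adjusted p = 0.13), and its median was -0.16 without FDCA 1 and -0.11 without LUFA 3.

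HMF arrays were higher for replication, repair and germ-line genes and lower for muscle, nerve and P450 genes, and the gap between the replication and muscle medians was 2.22. A trend with the GC content or signal of the probes was argued against as the whole cause, since the gap was 2.30 after that trend was removed, and so was LUFA 3 alone, since the gap was 2.08 without it. A larger share of germ-line or egg RNA, which would dilute all body transcripts alike, may add to the pattern and stayed open as the whole cause, since the shift of -0.74 of muscle genes relative to cuticle genes had a 95% interval of -1.59 to 0.11. Muscle genes shifted by -1.02 relative to immune genes (-1.56 to -0.49), but this decided nothing, as immune genes went both ways, with quartiles of -1.13 and 0.75 that held the muscle median of -1.01. Unlike those of the list scores, both intervals came from the spread of the HMF and LUFA arrays alone. A direct response to HMF was not tested apart from this.

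The FDCA and HMF differences from LUFA correlated at r of 0.631 over all probes, beside 0.638 for TCA and FDCA (0.605 beside 0.555 with slide as a block, 0.648 beside 0.589 with quantile normalisation), and those of FDCA itself on slides 1 and 2 correlated at -0.257. Shared LUFA arrays could produce part of this, and differences taken from separate LUFA arrays correlated at r between 0.137 and 0.36 for FDCA and between -0.176 and 0.243 for TCA, which decided nothing with so few arrays. With slide as a block, 2 of 100 simulations of unchanged groups reached the observed covariance of 0.431, where their mean was 0.0945. The simulated r reached 0.957, so these simulations do not give the level of sharing alone and decided nothing. FDCA and HMF shared slide 1 alone, so slide and treatment could not be separated fully, and whether both furans shared a response stayed open.

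Probes with a match to the first 7 bases of a sequencing adapter were less often above background, with 52.1% of 1663 kept against 80.1% of the others. The adapter part was taken to run from that match to the end of the probe. The bases after the match were not checked, so matches by chance can be among these probes. Of probes with an adapter part of up to 15 bases by that rule 66.6% were kept, against 22.5% with over 25 bases. Adapter bases failing to pair with the sample could give this gap of 44.1 percentage points. Probes with a short adapter part already lay 13.5 percentage points below those without one, which rarer transcripts behind them could give. Both explanations stayed open. No biological explanation was tested.

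Each comparison of 3 with 3 arrays allows 10 splits, which are too few for a share under 0.05. In the other splits a true group difference counts as spread within groups, which lowers their calls. Their counts therefore give no level of chance. The real split called 9496 probes for HMF against LUFA and 4415 for HMF against FDCA, where the highest of the other splits called 0, and 1 of 10 splits was as large. For HMF against TCA it called 7104, the highest of the others called 11, and 1 of 10 was as large. For TCA against LUFA and FDCA against LUFA all 10 splits called 0. For FDCA against TCA the real split called 0, all 10 were as large, and the split that set TCA 1, FDCA 1 and FDCA 3 apart called 39, which points to a structure of the samples other than their groups. That split holds both arrays of slide 1 and 1 of the 3 arrays on slide 2, so it follows the slides in part, and 0 probes passed for FDCA against TCA when slide was a block.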
